A study of Mus musculus with 12 samples.

How the data were processed

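RNA was measured in the trigeminal nerve of 12 mouse samples, 6 labelled normal nerve (Nf1 flox/flox without PostnCre) and 6 labelled plexiform neurofibroma (Nf1 flox/flox with PostnCre). Per the labels' protocols, total RNA was extracted with a column kit and polyA RNA libraries were made with a stranded mRNA kit; a TruSeq kit is named in the same label, so the kit of each library is uncertain. Per the submitters' processing notes, FastQC, STAR 2.4.2a, Salmon 0.60 and DESeq2 were used with build mm10; the notes give these tools no role or order. The annotation the authors counted on, and whether counting used strand, are not given in the sources used here.

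The authors deposited 1 table of estimated counts per gene symbol, 47480 symbols by 12 samples, with no normalization. Between 84.1% and 86.5% of the values of a library were whole numbers within 0.001, and the rest were fractions, as estimated counts give where reads fit more than 1 transcript or gene. The expected counts were rounded to whole numbers before any test. Reads that fit near-identical genes can be shared out between them by such estimates, so values of paralogs and pseudogenes are uncertain. Each column was assigned to its sample by its title. Total counts ran from 14160025 to 19989351 per library.

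Symbols were matched to GENCODE vM21 on GRCm38, the same assembly as mm10. Of the 47480 symbols, 45187 matched directly, 605 matched through an older symbol in RefSeq, and 1688 did not match. Coordinates are 1-based positions of whole genes in that annotation, and transcript length is that of the longest annotated transcript.

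Genes were filtered by expression with filterByExpr, which left 17236. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, robust fitting and no covariate. The p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. CPM values use TMM-scaled library sizes, and fold changes are plexiform neurofibroma over normal nerve. Every adjusted p of a gene comes from this test unless another tool is named. The labels give no sex, age, litter or batch, and they do not state that the samples came from separate animals. The p-values therefore measure the spread between these samples.

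For 36 gene lists, a score per library was the mean log2 CPM (prior count 2) of the measured members. Group means of the scores were compared by a two-sided exact permutation test over the 924 splits of 6 against 6, for which the smallest possible p is 0.00217. These p-values were adjusted over the 36 lists. Beside them, fry and camera of limma 3.58.1 were run, camera with a preset correlation of 0.01 and with an estimated one. fry tests whether the genes of a list move one way on balance, and camera sets them against all other tested genes. In the results, an adjusted p given with an estimated correlation comes from camera, not from the permutation test.

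The lists, the tests, the alternative settings and the rule for named genes were fixed before the data were examined. The rule named Nf1 and Postn; the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap, with a mean CPM of at least 5 and no placeholder symbol; up to 4 called members of each list in order of p-value, or the 1 or 2 with the smallest p where none was called; and any member of the lists for cyclin D, CDK4/6 and RB regulators and for ERK output. A few called list members outside this rule are named where a count of 5 or fewer would else leave them out, and are said to be chosen after their values were seen. Some genes the rule gives are not reported here. Those settings were RLE and upper-quartile factors, no filter, a filter at CPM above 1 in at least 6 samples, DESeq2 1.42.0, limma-voom with sample weights, and 4 covariates (sex-linked transcripts and the sensory neuron, CNS and skeletal muscle scores). Each library was also left out in turn, and list scores were recomputed as medians and as mean z-scores. A correction for transcript length (per-library lowess, span 0.3) and a fit without 3 libraries that stood apart were chosen after seeing the data.

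The count test was tested on simulated data for the comparison of 6 against 6 libraries, drawn from the real means, library sizes and dispersions over 17019 genes with 200 genes changed by known folds outside the cholesterol synthesis and interferon response lists, whose members were changed 2-fold in opposite directions. It recovered 35.8% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 95.5% of those changed 4-fold. The 200 genes were not drawn from those with the lowest mean CPM, so these rates do not cover genes near the floor. Of its calls, 4.62% were unchanged genes. With no gene changed it made 0 calls. Counts were drawn for each gene on its own, without outlying libraries or a length trend, so these figures hold for such data only. Depth and the spread between samples thus leave many changes of 1.5-fold or less undetected.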

Results

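Gene expression was measured by RNA sequencing in trigeminal nerve, the main sensory nerve of the face. There were 6 samples of normal nerve and 6 of plexiform neurofibroma. Plexiform neurofibroma is a benign nerve sheath tumour that arises when Schwann lineage cells lose Nf1, which encodes neurofibromin, a brake on RAS. All mice carried floxed Nf1, and only the tumour group carried a Cre recombinase named for Postn. Genotype and tumour state therefore coincide. The series title names combined inhibition of CDK4/6 and ERK1/2, so genes of the cell cycle entry machinery and of ERK output were examined as lists of their own. Total counts averaged 16934792 ± 2517371 (SD, n = 6) in normal nerve and 17726505 ± 1578295 (SD, n = 6) in plexiform neurofibroma (two-sided exact permutation p = 0.524).

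The deleted gene was examined first. Nf1 (chromosome 11, 79339693 to 79581612, GRCm38) averaged 131 CPM ± 35.8 (SD, n = 6) in normal nerve and 83.8 CPM ± 8.13 (SD, n = 6) in the tumours. The 6 normal libraries measured 132.7, 85.55, 149.4, 173.2, 155.2 and 90.55 CPM, and the 6 tumour libraries measured 93.09, 86.39, 86.82, 79.88, 69.55 and 86.91 CPM. Its log2 fold change was -0.65 (SE 0.16, edgeR adjusted p = 0.0179), and the groups overlapped. The count covers the whole gene, so removal of a floxed part need not lower it, and Evi2a, Evi2b and Omg lie within the gene. After the length correction the log2 fold change of Nf1 was -0.45 (edgeR adjusted p = 0.0455). Postn (chromosome 3, 54361109 to 54391037), which encodes the matrix protein periostin, rose 6.37-fold, from 22.1 CPM ± 6.44 to 141 CPM ± 53.6 (SD, n = 6 each, edgeR adjusted p = 0.00083).

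In plexiform neurofibroma, genes of Schwann cells and myelin, of extracellular matrix and basement membrane, of the D-type cyclin machinery, of ERK output and of the interferon response rose. In camera with an estimated correlation, each of these lists had an adjusted p = 0.443. ERK output also missed the threshold of the score test when scored by its median member (exact permutation, adjusted p = 0.432). Of 17236 genes tested, 1730 were higher and 1488 were lower in the tumours. Changes of at least 2-fold were mostly increases, with 372 genes higher and 61 lower. The groups did not overlap for 1273 of the tested genes, or 7.39%, against 0.217% expected by chance. Of the 3218 calls, 1755 were made whichever single library was left out. Without plexiform neurofibroma replicate 4 the count was 1893, without normal nerve replicate 5 it was 2098, and without normal nerve replicate 6 it was 5031, with 2487 lower and 657 changed at least 2-fold. Higher genes numbered 1092 without plexiform neurofibroma replicate 4. Lower genes numbered 801 without that library, 942 and 934 without plexiform neurofibroma replicates 2 and 6, and 976 and 907 without normal nerve replicates 4 and 5.

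The largest rise under the naming rule was that of Pmp2 (chromosome 3, 10179851 to 10183929), which encodes a fatty acid-binding protein of peripheral myelin. Pmp2 averaged 6.94 CPM ± 4.2 in normal nerve and 181 CPM ± 71.1 in the tumours, a 26.1-fold rise (SD, n = 6 each, edgeR adjusted p = 0.00115). Klk8, a serine protease, rose 11.8-fold, and Them5, an acyl-CoA thioesterase, rose 8.45-fold. The interferon-inducible Ifi27l2a rose 8.31-fold, and Ccl11, the chemokine eotaxin, rose 6.95-fold. The transcription factors Foxs1, Meox1 and Meox2 rose 6.16-fold, 5.1-fold and 4.86-fold, and Nkd2, an inhibitor of WNT signalling, rose 4.74-fold.

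**Figure D1:**
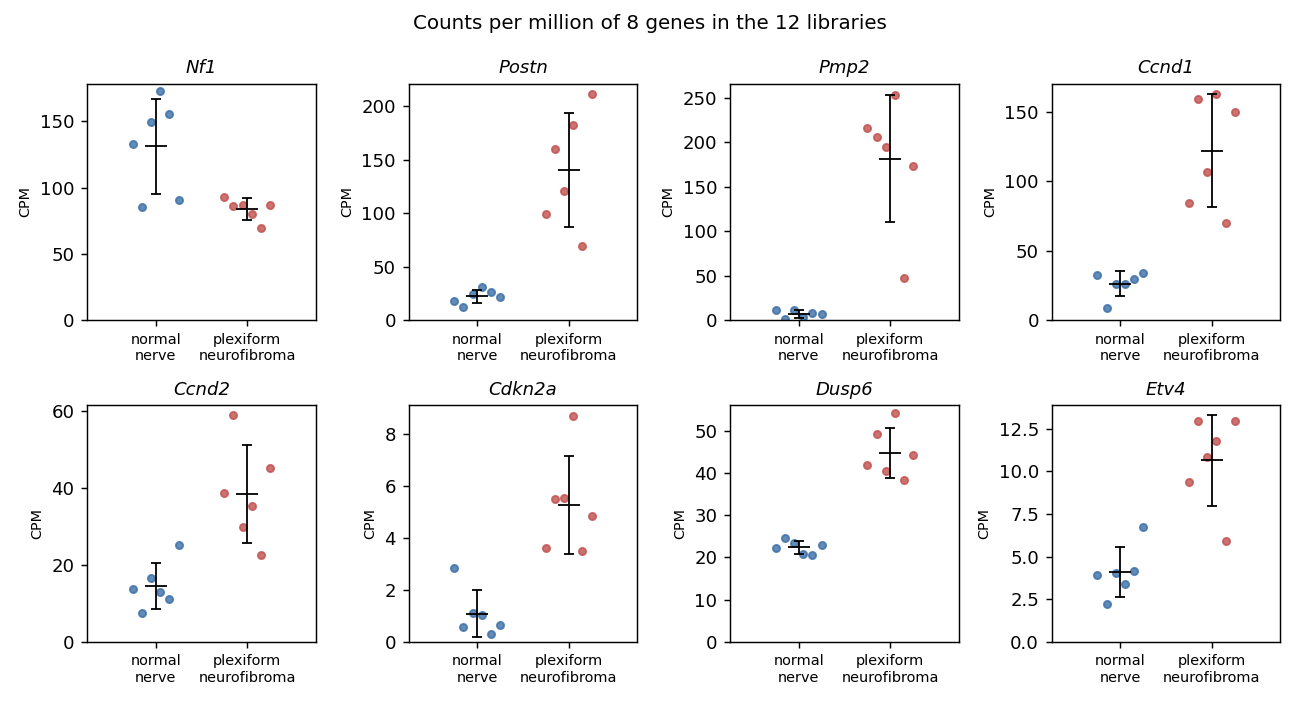
CPM of Nf1, Postn, Pmp2, Ccnd1, Ccnd2, Cdkn2a, Dusp6 and Etv4, on linear axes from 0, with 1 point per library (6 per group), the mean as a horizontal mark and the SD as error bars. Every tumour library lay above every normal library for Postn, Pmp2, Ccnd1, Cdkn2a and Dusp6, and the groups overlapped for Nf1, Ccnd2 and Etv4.

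Falls were smaller. Susd6 fell from 116.3 CPM ± 25.9 to 53.3 CPM ± 4.05 (SD, n = 6 each), a fold of 0.458 (edgeR adjusted p = 0.00115). Lancl3, Kndc1 and Mapk4 fell to 0.382, 0.503 and 0.513 of the normal level. Zdbf2 and the RNA-binding splicing regulator Nova2 had folds of 0.355 and 0.399, or log2 fold changes of -1.49 and -1.33. Both were highest in normal nerve replicate 6, as was Kndc1, and without that library they were at -0.79 and -0.70 (edgeR adjusted p = 0.00607 and 0.00373). Both lost their call without any 1 of plexiform neurofibroma replicates 2 to 6 (highest edgeR adjusted p = 0.0683 and 0.0759), with no filter (0.0645 and 0.0718) and after the length correction (0.0645 and 0.0604).

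Schwann cell genes rose. Of 14 measured members of the Schwann cell lineage list, 9 were higher and none was lower (11 higher adjusted over the list alone). The score rose by 0.74 log2 (exact permutation, adjusted p = 0.0223; adjusted p = 0.443 with an estimated correlation). S100b, a calcium-binding Schwann cell marker, rose 1.74-fold from 879.9 CPM ± 96.4 to 1531 CPM ± 170 (SD, n = 6 each). Cdh19, an adhesion molecule of the lineage, rose 1.97-fold, Cadm4 rose 2.19-fold and the transcription factor Foxd3 rose 2.3-fold. Normal nerve replicate 2 had the lowest Schwann cell score, 6.53, and the lowest myelin score, 5.84.

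Myelin genes rose as well. The score of the myelinating Schwann cell list rose by 0.90 log2, with 6 of 20 members higher, none lower and 8 higher adjusted over the list alone (exact permutation, adjusted p = 0.026; adjusted p = 0.443 with an estimated correlation). Pmp22, a structural protein of compact peripheral myelin, rose 2.38-fold, and Gldn, which acts at nodes of Ranvier, rose 2.98-fold. Members called higher numbered 12 without normal nerve replicate 1, and 1 was lower without normal nerve replicate 6. This score missed the threshold without any 1 of plexiform neurofibroma replicates 1, 2, 4 and 6 (highest adjusted p = 0.0519), and was 0.57 log2 without the 3 libraries that stood apart. In the list for non-myelinating and repair Schwann cells, 4 of 18 members were higher (6 adjusted over the list alone), among them the growth factors Btc at 2.43-fold and Lif at 3.09-fold. Its score difference of 0.34 log2 missed the threshold (exact permutation, adjusted p = 0.0519). It passed at 0.39 log2 without normal nerve replicate 6 (adjusted p = 0.0341) and at 0.40 log2 without plexiform neurofibroma replicate 3 (adjusted p = 0.0312). Of 22 cholesterol synthesis genes, which supply myelin sterol, 10 were higher and none lower (13 higher adjusted over the list alone). The count was 5 without any 1 of normal nerve replicate 5 and plexiform neurofibroma replicates 2 and 6, and 6 without plexiform neurofibroma replicate 5. Their score rose by 0.27 log2 (exact permutation, adjusted p = 0.0223; adjusted p = 0.443 with an estimated correlation), with Nsdhl at 1.41-fold and Mvd at 1.56-fold.

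Matrix genes rose. Of 25 fibrillar collagen and matrix genes, 15 were higher and none lower (18 higher and 1 lower adjusted over the list alone), and the score rose by 1.15 log2 (exact permutation, adjusted p = 0.0223; adjusted p = 0.443 with an estimated correlation). Without plexiform neurofibroma replicate 2 the rise was 1.02 log2 (adjusted p = 0.0519). Lox, which cross-links collagen, rose 3.79-fold from 13.4 CPM ± 2.58 to 50.9 CPM ± 19.7 (SD, n = 6 each), Fbn2 rose 3.92-fold and Col5a2 rose 2.09-fold. Of 19 basement membrane genes, 12 were higher and none lower (13 adjusted over the list alone). Their score rose by 0.78 log2 (exact permutation, adjusted p = 0.0223; adjusted p = 0.443 with an estimated correlation), with Col15a1 at 3.42-fold, Col18a1 at 2.99-fold, Col4a2 at 1.91-fold and Lama4 at 1.82-fold. Of 17 matrix proteases and inhibitors, 6 were higher (6 higher and 1 lower adjusted over the list alone), among them Timp1 at 4.45-fold, Mmp2 at 3.45-fold and Mmp19 at 2.36-fold. That score difference was 0.45 log2 (exact permutation, adjusted p = 0.0974), and 0.57 log2 without normal nerve replicate 6 (adjusted p = 0.03). Leaving out normal nerve replicate 1 gave 1 lower member.

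The D-type cyclins and their kinases rose, as did INK4 inhibitors. Of 18 measured cyclin D, CDK4/6 and RB regulator genes, 8 were higher and none lower (8 higher and 1 lower adjusted over the list alone). Leaving out normal nerve replicate 6 gave 1 lower member. The score rose by 0.69 log2, and the groups did not overlap (exact permutation, adjusted p = 0.0223; adjusted p = 0.443 with an estimated correlation). Ccnd1 (chromosome 7, 144929931 to 144939925) rose 4.65-fold, from 26.3 CPM ± 9.16 to 122 CPM ± 40.5 (SD, n = 6 each, edgeR adjusted p = 0.00191). Its annotated range overlaps that of Oraov1 on the other strand. Ccnd2 and Ccnd3 rose 2.65-fold and 2.61-fold, and their partner kinases Cdk4 and Cdk6 rose 1.37-fold and 1.69-fold. Among the CDK4/6 inhibitors, the neighbours Cdkn2a (chromosome 4, 89274471 to 89294653) and Cdkn2b rose 4.79-fold and 3.62-fold, and Cdkn2c rose 2.97-fold. Cdkn2a averaged only 1.08 CPM ± 0.914 in normal nerve and 5.29 CPM ± 1.89 in the tumours (SD, n = 6 each). Its count covers all transcripts of the gene, so the INK4 product was not measured apart from others. The log2 fold changes of Rb1 and Cdkn1b were -0.08 and -0.10 (edgeR adjusted p = 0.37 and 0.68). Rb1 was at -0.0479 without plexiform neurofibroma replicate 5, and Cdkn1b ran from -0.18 without normal nerve replicate 6 to 0.0169 without normal nerve replicate 1.

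Few replication and mitosis genes were called, but 21 of the 23 measured G2/M genes averaged under 5 CPM. Log2 fold changes lay above 0 for 17 of 26 replication and G1/S genes and for 18 of 23 G2/M genes. DESeq2 called 4 and 2 of these higher and limma-voom 5 and 2, and limma-voom called 1 replication gene lower. Of 26 replication and G1/S genes, 2 were higher and none lower (2 adjusted over the list alone), Mcm7 at 1.37-fold and Uhrf1 at 2.27-fold. Uhrf1 lay near 1 CPM and lost its call without any 1 of normal nerve replicates 4 and 5 and plexiform neurofibroma replicates 2, 4 and 6 (highest edgeR adjusted p = 0.0587). Of 23 G2/M genes, Cenpf alone was called, at 2.47-fold from 0.907 CPM, and 0 were called adjusted over the list alone; it lost the call without any 1 of normal nerve replicates 1 and 5 and plexiform neurofibroma replicates 2, 4 and 6 (highest edgeR adjusted p = 0.0724). The score differences were 0.16 log2 and 0.28 log2 (exact permutation, adjusted p = 0.0659 and 0.144). Without normal nerve replicate 6 the replication and G1/S score passed at 0.20 log2 (adjusted p = 0.026), with 4 members higher and 1 lower. In the G2/M list 4 members were higher without normal nerve replicate 3, and 2 without normal nerve replicate 4 or plexiform neurofibroma replicate 5.

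ERK output genes rose. Of 20 members, 8 were higher and 1 was lower (9 and 1 adjusted over the list alone), and the score rose by 0.43 log2 with groups that did not overlap (exact permutation, adjusted p = 0.0223; adjusted p = 0.443 with an estimated correlation). Without any 1 of plexiform neurofibroma replicates 1, 2, 4 and 6, 5 members were higher. The lower member, the ERK pathway inhibitor Spred2, had a log2 fold change of -0.30 and lost its call without any 1 of normal nerve replicates 2 to 5 and plexiform neurofibroma replicates 2, 4 and 6 (highest edgeR adjusted p = 0.0747). Scored by the median member, the difference was 0.12 log2 (adjusted p = 0.432). Dusp6 (chromosome 10, 99263231 to 99267489), the ERK phosphatase induced by ERK itself, rose 2-fold, from 22.4 CPM ± 1.58 to 44.8 CPM ± 5.98 (SD, n = 6 each, edgeR adjusted p = 0.000297). The ETS factor Etv4 rose 2.62-fold, the feedback inhibitor Spry1 rose 2.14-fold and Phlda1 rose 1.88-fold. Ccnd1 is a member of this list too. The log2 fold change of Etv5 was 0.18 (edgeR adjusted p = 0.335), and 0.094 without normal nerve replicate 6.

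The kinase cascade itself showed no balance to either side. Of 23 RAS-ERK core components, 3 were higher and 2 lower (3 and 3 adjusted over the list alone), and 4 were lower without normal nerve replicate 6. The RAS-family GTPases Rras, Mras and Rras2 rose 1.66-fold, 1.6-fold and 1.41-fold, and the adaptor Grb2 fell to 0.828 but was not called with no filter (edgeR adjusted p = 0.0556). The exchange factor Sos1, chosen after its values were seen, had a fold of 0.75. Sos1 lost its call without any 1 of normal nerve replicates 3, 4 and 5 and plexiform neurofibroma replicates 2, 4 and 6 (highest edgeR adjusted p = 0.0726). The score difference was 0.02 log2 (exact permutation, adjusted p = 0.857), while the median member was at -0.04 log2. The difference ran from -0.0222 log2 without normal nerve replicate 6 to 0.038 log2 without normal nerve replicate 4. Of 24 receptor tyrosine kinases, 3 were higher and 3 lower (6 and 6 adjusted over the list alone; score difference 0.11 log2, exact permutation, adjusted p = 0.448), and the median member was at -0.02 log2. The score difference was 0.0608 log2 without normal nerve replicate 2 and 0.19 log2 without normal nerve replicate 6 (adjusted p = 0.704 and 0.136). Kinases called numbered 5 higher and 6 lower without normal nerve replicate 6, and 1 was higher without any 1 of normal nerve replicates 2, 4 and 5 and plexiform neurofibroma replicates 2 and 4. Axl rose 2.63-fold, while the neurotrophic receptors Ntrk3 and Ret fell to 0.695 and 0.687. Bulk RNA does not tell whether neurons or other cells hold these changes. After the length correction Ntrk3 was not called (edgeR adjusted p = 0.0696). Pdgfrb and Erbb2, chosen after their values were seen, had folds of 1.45 and 1.65. Both lost their call without any 1 of normal nerve replicates 2, 4 and 5 and plexiform neurofibroma replicates 2 and 4, and Erbb2 also without normal nerve replicate 3 or plexiform neurofibroma replicate 6 (highest edgeR adjusted p = 0.0589 and 0.0942). Of 24 growth factor ligands, 6 were higher and 1 lower (8 and 2 adjusted over the list alone; score difference 0.30 log2, exact permutation, adjusted p = 0.0668). That score passed at 0.35 log2 without normal nerve replicate 6 (adjusted p = 0.0341), where 10 members were higher and 4 lower, and at 0.36 log2 without plexiform neurofibroma replicate 5 (adjusted p = 0.0312). Hbegf, a ligand of the EGF receptor, rose 4.3-fold from 12.7 CPM ± 5.21 to 54.6 CPM ± 18.6 (SD, n = 6 each). Pdgfa and the macrophage growth factor Il34 rose 1.69-fold and 1.64-fold. The lower member, Vegfa, chosen after its values were seen, had a fold of 0.822 and lost its call without any 1 of normal nerve replicates 2 to 5 and plexiform neurofibroma replicates 2, 4 and 6 (highest edgeR adjusted p = 0.0853).

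**Figure D2:**
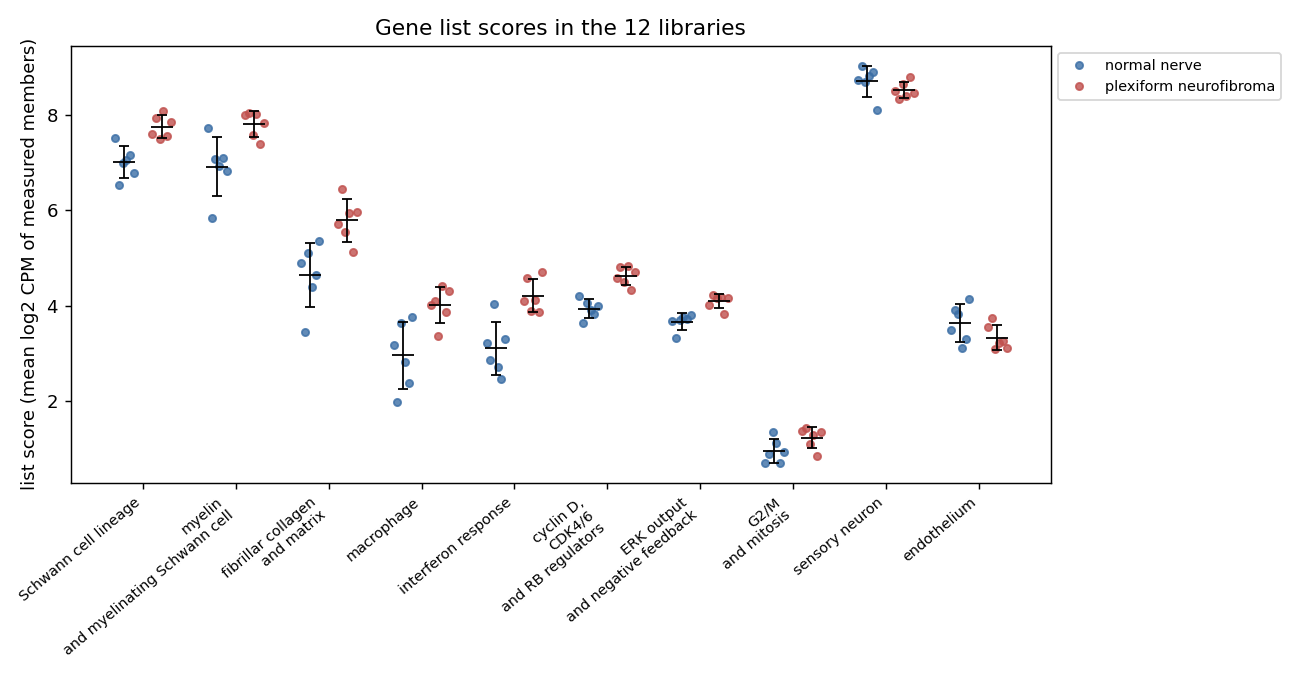
Scores of 10 gene lists (mean log2 CPM of the measured members), with 1 point per library, 6 per group, the mean as a horizontal mark and the SD as error bars. The cyclin D and ERK output scores separated the groups fully, with rises of 0.69 and 0.43 log2, while the sensory neuron and endothelium scores overlapped.

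Macrophage and interferon genes were higher. Of 18 macrophage genes, 6 were higher and 1 lower (13 and 1 adjusted over the list alone), and the score rose by 1.05 log2 (exact permutation, adjusted p = 0.0354; adjusted p = 0.443 with an estimated correlation). Aif1, a macrophage marker, rose 3.35-fold from 2.4 CPM ± 1.96 to 8.07 CPM ± 1.52 (SD, n = 6 each). The lower member, the scavenger receptor Cd163, chosen after its values were seen, had a fold of 0.549. Cd163 lost its call without any 1 of normal nerve replicates 3 to 5 and plexiform neurofibroma replicates 1, 2, 3, 5 and 6 (highest edgeR adjusted p = 0.103). Of the 18 genes, 3 were higher without any 1 of normal nerve replicates 1 and 2 and plexiform neurofibroma replicates 1 and 2, 2 without any 1 of normal nerve replicates 4 and 5 and plexiform neurofibroma replicate 6, 1 without plexiform neurofibroma replicate 4, 11 without plexiform neurofibroma replicate 3 and 12 without normal nerve replicate 6. The macrophage score missed the threshold without any 1 of normal nerve replicates 2, 4 and 5 and plexiform neurofibroma replicates 1, 2, 4, 5 and 6 (highest adjusted p = 0.0935). Of 22 interferon response genes, 11 were higher and none lower (19 adjusted over the list alone). The count was 19 without normal nerve replicate 3. That score rose by 1.11 log2 (exact permutation, adjusted p = 0.026; adjusted p = 0.443 with an estimated correlation). Ifit1 rose 2.83-fold, the interferon regulatory factor Irf7 rose 2.55-fold, Mx2 rose 1.96-fold and the RNA sensor Ddx58 rose 1.52-fold. Of 13 chemokines, 3 were higher (4 adjusted over the list alone), among them Ccl2 at 4.37-fold (score difference 1.11 log2, exact permutation, adjusted p = 0.0727). The 3 became 1 without normal nerve replicate 5 or plexiform neurofibroma replicate 6, and 5 without normal nerve replicate 3 or 6. The chemokine score passed at 1.36 log2 without normal nerve replicate 3 (adjusted p = 0.026) and at 1.32 log2 without normal nerve replicate 6 (adjusted p = 0.0346).

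Other immune lists gave few calls. Among 14 dendritic cell and antigen presentation genes, 2 were higher and 1 lower (2 and 1 adjusted over the list alone), with H2-DMa, which loads peptides on MHC class II, at 1.98-fold (score difference 0.56 log2, exact permutation, adjusted p = 0.133). The lower member, the cytokine receptor Flt3, had a log2 fold change of -0.37 and lost its call without any 1 of normal nerve replicates 4 and 5 and plexiform neurofibroma replicates 1, 2, 4 and 6 (highest edgeR adjusted p = 0.0659). The T cell and NK cell score passed at a difference of 0.41 log2 (exact permutation, adjusted p = 0.0223; adjusted p = 0.75 with an estimated correlation). Only 6 of its members were measured, 1 was called and 0 were called adjusted over the list alone. That member, the NK cell receptor Klrb1c, rose 3.1-fold from 0.948 CPM and lost its call without any 1 library other than normal nerve replicate 1 (highest edgeR adjusted p = 0.103). With no filter the list missed the threshold (adjusted p = 0.211). Of the mast cell, B cell and neutrophil genes edgeR called 0, as did DESeq2 and limma-voom, and at an unadjusted p under 0.05 it gave 2, 0 and 0. With single libraries left out, edgeR called at most 1 gene of each. Their score differences were 0.62, 0.61 and 0.24 log2 (exact permutation, adjusted p = 0.224, 0.203 and 0.767). Without normal nerve replicate 3 the dendritic cell and B cell scores passed at 0.75 and 0.88 log2 (adjusted p = 0.0223 and 0.048), and 5 dendritic cell genes were higher. The dendritic cell and mast cell differences were 0.30 and 0.38 log2 without normal nerve replicate 2 (adjusted p = 0.353 and 0.45), and the B cell difference was 0.38 log2 without plexiform neurofibroma replicate 6 (adjusted p = 0.36). The neutrophil difference ran from 0.0152 log2 without plexiform neurofibroma replicate 5 to 0.58 log2 without normal nerve replicate 3 (adjusted p = 0.972 and 0.381). Of the 8 mast cell genes, 6 had a log2 fold change above 0, and the median was 0.54. Slc18a2 and Kit lay below 0, at -1.50 and -0.34 (edgeR adjusted p = 0.12 and 0.136). Slc18a2 was at -0.13 without normal nerve replicate 6 (edgeR adjusted p = 0.383), and Kit was called at -0.46 without plexiform neurofibroma replicate 3 (edgeR adjusted p = 0.0404).

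Neuronal and vascular lists held few called genes. Of 23 sensory neuron genes, 1 was lower (1 adjusted over the list alone), the synaptic protein Snap25 at a fold of 0.722, and 3 had a log2 fold change above 0. DESeq2 called 3 of them lower and limma-voom 8. The score difference was -0.18 log2 (exact permutation, adjusted p = 0.348), and -0.30 log2 without normal nerve replicate 6 (adjusted p = 0.0341), where 11 were lower, but -0.11 log2 without normal nerve replicate 2 (adjusted p = 0.661). Without plexiform neurofibroma replicates 3 and 5 in turn, 2 and 3 were lower. Of 16 endothelial genes, 1 was lower, Cdh5 at a fold of 0.619, and 0 were called adjusted over the list alone (score difference -0.31 log2, exact permutation, adjusted p = 0.224). The endothelial count was 2 without normal nerve replicate 5 or 6, and the score difference was -0.20 log2 without normal nerve replicate 6. Cdh5 lost its call without any 1 of normal nerve replicates 2 and 3 and plexiform neurofibroma replicates 3 to 6 (highest edgeR adjusted p = 0.0633). Of 13 pericyte and smooth muscle genes, Cspg4 alone was called (1 adjusted over the list alone), at 3.04-fold, and of 10 satellite glia genes, Lgi4 alone was called (1 adjusted over the list alone), at 2.07-fold. Those score differences were both 0.19 log2 (exact permutation, adjusted p = 0.767 and 0.462), and the satellite glia score passed at 0.38 log2 without normal nerve replicate 6 (adjusted p = 0.026), where 5 members were higher, but differed by 0.13 log2 without normal nerve replicate 2 (adjusted p = 0.704). The pericyte difference ran from -0.0768 log2 without plexiform neurofibroma replicate 2 to 0.46 log2 without normal nerve replicate 6. Without any 1 of normal nerve replicates 3, 4 and 6, 1 satellite glia gene was lower. The fibroblast and perineurial cell lists each had 3 higher members (adjusted over the list alone, 3 higher in each and 1 lower in the perineurial list), with score differences of 0.54 and 0.00217 log2 (exact permutation, adjusted p = 0.139 and 0.985), and the median perineurial member was at -0.27 log2. The perineurial difference ran from -0.0499 log2 without normal nerve replicate 2 to 0.0845 log2 without normal nerve replicate 6. Ccl11 in the fibroblast list and Sfrp5 in the perineurial list, at 1.45-fold, were among the higher members. The fibroblast count was 1 without any 1 of normal nerve replicate 4 and plexiform neurofibroma replicates 2, 4 and 6, and the perineurial count was 1 without any 1 of normal nerve replicate 5 and plexiform neurofibroma replicates 4 and 6. Without normal nerve replicate 6 or plexiform neurofibroma replicate 5, 1 perineurial gene was lower. Sfrp5 was not called after the length correction (edgeR adjusted p = 0.0563).

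Markers of neighbouring tissues set some libraries apart. Skeletal muscle scored 6.53 in plexiform neurofibroma replicate 1, against 1.25 to 1.39 in the other tumours, and 4.76 and 2.50 in normal nerve replicates 3 and 4. CNS glia scored 6.07 in normal nerve replicate 6. Normal nerve replicate 2 had the lowest fibrillar matrix score, 3.45, and the lowest macrophage score, 1.98. Of the CNS glia, skeletal muscle, adipocyte and red blood cell genes edgeR called 0, against 3, 0, 2 and 1 at an unadjusted p under 0.05. DESeq2 and limma-voom each called 2 CNS glia genes and 0 of the others. With single libraries left out, edgeR called at most 1 gene of any of these lists. These lists had score differences of -0.20, 0.10, 0.07 and -0.89 log2 (exact permutation, adjusted p = 0.871, 0.928, 0.985 and 0.404). With single libraries left out, the CNS glia difference ran from -0.57 log2 without normal nerve replicate 4 to 0.29 log2 without normal nerve replicate 6. The skeletal muscle difference ran from -0.77 log2 without plexiform neurofibroma replicate 1 to 0.63 log2 without normal nerve replicate 3, and the adipocyte difference from -0.50 log2 without plexiform neurofibroma replicate 1 to 0.26 log2 without plexiform neurofibroma replicate 6. The red blood cell difference was -0.39 log2 without normal nerve replicate 6. The epithelium score rose by 0.39 log2 over 5 measured genes, of which edgeR, DESeq2 and limma-voom called 0 and 0 had an unadjusted p under 0.05 (exact permutation, adjusted p = 0.0354; adjusted p = 0.443 with an estimated correlation). It missed the threshold without any 1 library other than normal nerve replicates 1 and 6, and without normal nerve replicate 2 the difference was 0.20 log2 (adjusted p = 0.542), and without normal nerve replicate 5 it was 0.24 log2 (adjusted p = 0.487). The bone and cartilage, immediate early and hypoxia lists differed by 0.25, 0.29 and 0.08 log2 (exact permutation, adjusted p = 0.348, 0.348 and 0.224). The immediate early score passed at 0.48 log2 without normal nerve replicate 6 (adjusted p = 0.0369), where 6 members were higher. The bone and cartilage difference was 0.46 log2 without plexiform neurofibroma replicate 5 (adjusted p = 0.156). They held 2, 1 and 2 higher members and 0, 1 and 0 lower members, with the same counts adjusted over the list alone. The median bone and cartilage member was at -0.17 log2. The cartilage collagen Col2a1 rose 2.81-fold, the immediate early gene Nr4a1 rose 1.75-fold and the vasodilator peptide gene Adm rose 2-fold. The bone and cartilage count was 1 without any 1 of normal nerve replicates 2, 4 and 5 and plexiform neurofibroma replicates 2, 4 and 6, and the hypoxia count was 1 without any 1 of normal nerve replicates 2 to 4. The lower immediate early member, the transcription factor Klf2, had a log2 fold change of -1.13 and lost its call without any 1 of normal nerve replicates 2, 3 and 6 and plexiform neurofibroma replicates 1, 3, 4, 5 and 6 (highest edgeR adjusted p = 0.0816).

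Calls also followed transcript length. In the shortest decile of longest transcripts (median 757 bases) 17.4% of genes were higher and 1.53% lower, and in the longest (median 8157 bases) 5.18% were higher and 22.5% lower. Across 16980 genes, which are not independent replicates, Spearman's rho of log2 fold change on length was -0.221. With a correction for length, 2587 genes were called, 1472 higher and 1115 lower, of which 2275 were called in the same direction without it, and all 11 list scores past the threshold stayed past it. In the 9 libraries left without normal nerve replicates 2 and 6 and plexiform neurofibroma replicate 1, 4210 genes were called. There all 11 kept their direction at an unadjusted exact p under 0.05, but none passed adjustment (lowest exact permutation adjusted p = 0.0952).

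**Figure D3:**
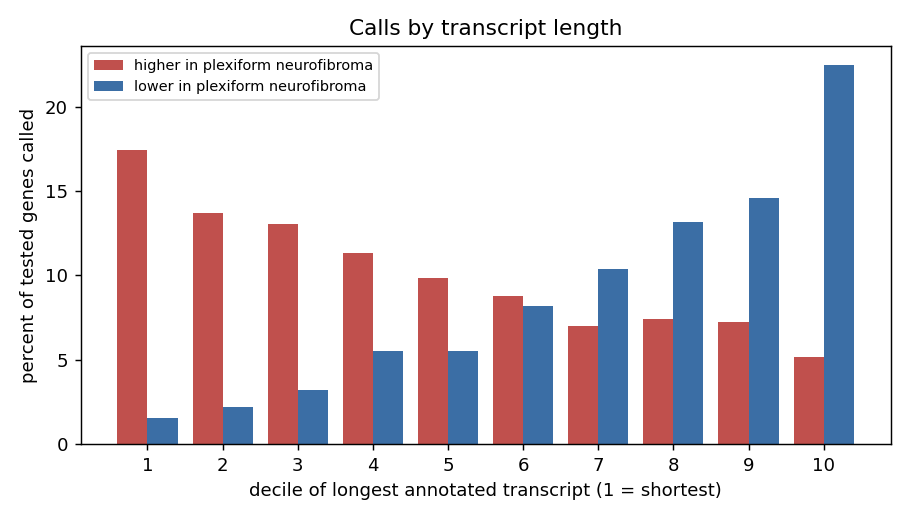
Percent of tested genes called higher or lower in plexiform neurofibroma (bars from 0) in each decile of the longest annotated transcript, with decile 1 the shortest. The share called higher went from 17.4% in the shortest decile to 5.18% in the longest, and the share called lower from 1.53% to 22.5%.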

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

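The tests of neuronal share against endothelium and of Pmp2 against the Schwann cell score were chosen after the results were seen, as were the length correction and the fit without 3 libraries. Of 300 sets of 6 values examined, 31 had a library whose gap from the nearest other, as a share of the range, exceeded Dixon's critical value. Chance gives about 1 in 20, here about 15.

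Normal nerve replicate 6 stood out in 11 of these 31. It was highest for Zdbf2 (gap ratio 0.748), Nova2 (0.743), Smim17 (0.768), Cit (0.729), Kndc1 (0.802), Vegfa (0.68), the monoamine transporter gene Slc18a2 (0.873) and the satellite glia score (0.705). It was lowest for Susd6 (0.753), Ret (0.656) and the sensory neuron score (0.64). Normal nerve replicate 2 stood out in 9. It was lowest for Ccl11 (0.742), Meox1 (0.629), Meox2 (0.719), Ccnd1 (0.796), Col15a1 (0.642), Mmp2 (0.64), Smoc2 (0.702) and the ERK output score (0.723), and highest for the adipocyte score (0.68). The cholesterol synthesis gene Mvd was highest in normal nerve replicate 1 (0.707).

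Among the tumours, replicate 1 was highest for the skeletal muscle score (0.974), the adipocyte score (0.767) and Hk2 (0.653). Replicate 5 was lowest for Pmp2 (0.775), Dusp4 (0.662) and the bone and cartilage score (0.672). Replicate 6 was highest for the interferon genes Ifit1 (0.877) and Irf7 (0.651), replicate 2 for Klrb1c (0.769) and replicate 3 for Kit (0.657).

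The splits argue against chance as the source of the count of changed genes. Of 100 splits drawn from the 462 possible, 1, the real one, reached its 3218 calls, and the highest other split gave 1 call. The evidence is a rank of 1 in 100 and not the gap in counts. A split that mixes the groups puts their difference into the spread within each side, which lowers its calls.

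Short transcripts were higher and long ones lower in the tumours. With the sensory neuron score in the model, rho was -0.232. That score differed by only -0.18 log2 between the groups and was lowest in normal nerve replicate 6. The adjustment therefore cannot rule out fewer neuronal transcripts as a cause. Without annotated pseudogenes and genes whose symbols start with Rpl or Rps and a digit, rho was -0.213, so those genes alone do not account for the trend. A difference in RNA or library preparation that acts on every cell type may contribute. Among 556 list members centred within their lists, rho was -0.164 (permutation of lengths within lists, p = 0.0002). That permutation took genes as its units, so its p does not measure the spread between libraries. Whether the tumours themselves hold shorter transcripts was not tested, and the design ties any such difference in handling to the groups.

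Schwann, matrix, macrophage and interferon lists were higher in the tumours. A lower share of neuronal tissue, if it raised every other cell type alike, would raise endothelium with Schwann cell genes. The Schwann cell score rose over the endothelium score by 1.05 log2, which argues against such an even rise alone for Schwann cell genes. Both lists were picked after their values were seen, so no p-value is given. The sensory neuron and endothelium scores differed by -0.18 and -0.31 log2. A lower share of tissue that holds both neurons and vessels is therefore not ruled out by this comparison. The matrix, macrophage and interferon scores were not set against endothelium. The length trend alone is argued against, since 11 of the 11 lists called higher stayed past the threshold after the correction. More Schwann cells, matrix-forming cells and macrophages, or higher expression per cell, stay open, because bulk RNA does not separate them and tumour state coincides with genotype.

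Pmp2 rose more than other Schwann cell genes. A larger share of Schwann cells of every kind, with no change per cell, would raise these genes alike. Pmp2, picked for its rise, exceeded the rise of the Schwann cell score by 4.18 log2, which argues against that. A shift between kinds of Schwann cell was not tested. A change of the whole chromosomal region is argued against too, since 7 tested neighbours within 500 kb had a median log2 fold change of 0.0318, although Chmp4c among them was at 1.27. A change that comes with tumour state or genotype stays open and was not tested.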

How the results depend on the processing

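The length correction and the fit without 3 libraries were chosen after seeing the data. None of the 3218 called genes, in any setting that tested it, and no called list changed direction, and Nf1 kept its call in all, between -0.74 and -0.55 log2 with single libraries left out. Without a filter, where 32206 genes were tested, 902 genes were lower and 1364 higher. The cause of these smaller counts was not tested. With limma-voom 5585 genes were called, 2878 higher and 2707 lower, 677 of them at least 2-fold, 3184 shared with the main test; the cause was not tested. Leaving out 1 library gave 1893 to 5031 changed genes, 1092 to 2544 higher, 801 to 2487 lower, 304 to 657 at least 2-fold and 7 to 19 lists; each lowest gene count lacked plexiform neurofibroma replicate 4, the 7 lists replicate 2, and each highest normal nerve replicate 6. With an estimated correlation 0 lists passed camera, against 14 with the preset one. These camera runs differed only in that correlation, preset at 0.01 and estimated from -0.03 (epithelium) to 0.89 (red blood cell). It was 0.46 for the Schwann cell lineage and 0.52 for the interferon response. With fry 14 lists passed, and the cause of its difference from camera was not tested. Without the 3 libraries 0 passed, where 126 splits allow no p under 0.00794. Of 108 named genes called, 76 kept the call in every leave-one-out fit. Values near 0 that were never called changed sign. With upper-quartile factors the perineurial score was -0.00282. By medians, skeletal muscle, pericyte and hypoxia scores were -0.0308, -0.34 and -0.0327, and by z-scores RAS-ERK core was -0.21. Its adjusted p was 0.737 with fry and 0.614 and 0.848 with camera, in the other direction. Without the 3 libraries, RAS-ERK core, CNS, skeletal muscle and adipocyte scores were -0.0608, 0.10, -1.10 and -0.34. With single libraries left out, the ranges were -0.18 to 0.0169 (Cdkn1b), -0.0499 to 0.0845 (perineurial), -0.77 to 0.63 (skeletal muscle), -0.0222 to 0.038 (RAS-ERK core), -0.57 to 0.29 (CNS), -0.50 to 0.26 (adipocyte) and -0.0768 to 0.46 (pericyte). Depth limits genes near 1 CPM, such as the G2/M list.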

Other observations

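The genes in this part were chosen after their values were seen, as was the test of the cyclin score against the G2/M score. Of 89 tested protein-coding genes whose symbols start with Rpl or Rps and a digit, 74 were higher and 2 lower in plexiform neurofibroma. Their median log2 fold change was 0.46. Most such symbols name ribosomal proteins, but S6 kinase genes (Rps6k) share the form, and Rplp0, Rplp1, Rplp2 and Rpsa lack it. No list score or set test covered these genes. Ribosomal protein transcripts are short, and after the length correction the median of the 89 was 0.34 and 63 were called. Oraov1, which overlaps the end of Ccnd1 on chromosome 7 (144915100 to 144931701), rose from 39.2 CPM ± 5.19 to 92.5 CPM ± 22.9 (SD, n = 6 each, edgeR adjusted p = 0.00115). Because strand use in counting is not given in the sources used here, reads of Ccnd1 cannot be told from those of Oraov1 where they overlap.

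D-type cyclins and CDK4/6 rose in the tumours, while few mitosis genes were called. Whether replication and mitosis transcripts rose in step with the D-type cyclins stays open. The cyclin D, CDK4/6 and RB regulator score rose over the G2/M score by 0.41 log2 (exact permutation p = 0.0195), but 21 of the 23 G2/M genes averaged under 5 CPM, the cyclin list holds INK4 inhibitors, and replication genes were not in this test.

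Some called genes stood far higher in 1 library than in any other. Obp1a, an odorant-binding protein, measured 766.5 CPM in plexiform neurofibroma replicate 3 and at most 5.7 CPM elsewhere, and Omp, a marker of olfactory neurons, measured 51.9 CPM there and at most 9.64 CPM elsewhere. Slc12a5 and Trank1 measured 154 CPM and 78.9 CPM in normal nerve replicate 6 and at most 1.85 CPM and 8.02 CPM elsewhere. Rpl34-ps1, a pseudogene whose reads can be shared with its parent gene, measured 40.6, 106.5 and 38.8 CPM in plexiform neurofibroma replicates 1, 4 and 5, and 2.59 to 5.75 CPM in the other 9 libraries. Sex-linked transcripts were balanced, with Xist above Ddx3y in 3 of 6 libraries of each group.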
